A study of Mus musculus with 3 samples.

How the data were processed

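H3K4me3 and H3K27me3 were measured by ChIP-seq in primordial germ cells sorted from pooled mouse gonadal regions at E11.5. Per the labels' protocols, chromatin was cross-linked in 0.25% formaldehyde for 10 min and sonicated. Each precipitation used 2.4 µg of antibody. Libraries were amplified for 20 cycles after precipitation and 15 cycles for input. Per the submitters' processing notes, Bowtie 0.12.7 and build mm9 were used. The authors deposited 1 list of regions per mark, named as contiguous ChromHMM regions. ChromHMM is a hidden Markov model program that segments the genome into chromatin states in fixed bins. Each file has 4 columns, the chromosome, start, end and region name, and holds positions in bp with no count, score or p-value. All starts and ends lay on a 200-bp grid. The version and settings of ChromHMM, the use of the input and the way the 2 replicates of a mark were combined are not given in the sources used here. The 3 samples fell into 3 groups of 1 (H3K4me3, H3K27me3 and input), so no test between replicates was possible and no replicate could be left out.

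The build was checked against chromosome lengths from GenomeInfoDb 1.38.1. On all 21 chromosomes compared, the last region ended inside the mm9 length, and on 9 it ended beyond the mm10 length. The gene table at hand is of assembly GRCm38, so none of its coordinates were used and no region was assigned to a gene. The planned promoter classes, the 33 gene lists fixed for them and the other cell type markers were therefore not analysed here, and whether other cells passed the sorting gate was not examined.

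Regions were counted as overlapping when they shared at least 1 bp. Coordinates are printed counting from 1. Percentages of regions have 95% Wilson intervals, which treat regions as independent and cover counting error only; regions are not replicates. Percentages of the genome are of 2655 Mb, the mm9 chromosomes without the mitochondrial genome. For random placement, all H3K27me3 regions of a chromosome were shifted together by a random distance, with wrap-around, 1000 times, and the overlapping length was compared by a two-sided empirical p. Assembly gaps and sequence to which reads cannot be mapped were not excluded from these shifts, which lowers the random overlap. Shares by width used 200 placements. Median widths were compared by two-sided permutation tests with 100000 resamples. The position of an enclosed H3K4me3 region was compared with 1000 random positions in the same H3K27me3 region. Regions were named by a rule: the 10 widest of each mark and the 10 longest overlap segments.

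Alternatives were regions wider than 400 bp, regions of a mark less than 1 kb apart joined, autosomes alone, an overlap of at least 400 bp or of 50% of the shorter region (100 placements each), single regions shifted by 0.1 to 1 Mb, and H3K4me3 moved in place of H3K27me3. These, the naming rule, the random placement of whole chromosomes, the tests of median width and the coverage by chromosome were fixed before the data were examined. Chosen after seeing the data were shifts between the first and last region of each chromosome, the lists without regions of identical ends, the lists without chromosome 5 from 111 to 122 Mb, the tests by width class, enclosed position and window, and the random median widths. Counts, lengths and shares of a chromosome relative to its length were called alike when within 1.5 times the reported value, and percentages of regions when inside its Wilson interval. Tested values were called alike when they kept their direction and their side of the 0.05 threshold, whatever their size. The procedure was tested on simulated data. Unrelated lists with 600 regions of the moved mark gave 0.824 times the random overlap (permutation p = 0.136). Planting 30% of those regions on the other mark gave 3.74 times (permutation p = 0.003, the smallest its placements can give). Simulated regions were drawn at a fixed width per mark and at uniform random positions. These runs therefore checked the calculation and not its calibration for regions that cluster along chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.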

Results

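Chromatin of primordial germ cells, the embryonic precursors of eggs and sperm, was profiled for a pair of histone modifications by chromatin immunoprecipitation and sequencing (ChIP-seq). Trimethylation of lysine 4 on histone H3 (H3K4me3) is typical of the promoters of active and CpG-rich genes, and trimethylation of lysine 27 (H3K27me3) is laid down by Polycomb complexes at silent genes. Chromatin carrying both is called bivalent. The cells were sorted from mouse gonadal regions of E11.5 embryos by a fluorescent Oct4 reporter, and 2 aliquots of 104000 and 97000 cells were each divided among an H3K4me3 precipitation, an H3K27me3 precipitation and an input control. The series holds 3 samples, each standing for 2 replicates. The called regions of each mark, 1 list for H3K4me3 and 1 for H3K27me3, were analysed, and the input was not analysed here. The lists give positions on mouse genome build mm9 and no read counts, so the depth behind each region is unknown and no value has an error between replicates. Intervals cover the counting of regions only. Genes were not assigned, because no annotation of this build was used here.

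H3K4me3 occupied many short regions and H3K27me3 fewer, wider ones. The H3K4me3 list held 47928 regions covering 50.2 Mb, which is 1.89% of the genome, with a median width of 800 bp (quartiles 200 and 1400 bp). The H3K27me3 list held 18731 regions covering 63.2 Mb, or 2.38% of the genome, with a median width of 1800 bp (quartiles 800 and 3600 bp). The widest H3K4me3 region measured 13.8 kb and the widest H3K27me3 region 142 kb. Regions over 10 kb made up 35.5% of the H3K27me3 length and 0.395% of the H3K4me3 length. Regions of a single 200-bp step numbered 12297 (25.7%) for H3K4me3 and 950 (5.07%) for H3K27me3. With regions of 400 bp or less left out, the number of H3K4me3 regions was 29120.

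The first comparison asked where both marks lay together, as bivalent chromatin would. The lists come from separate precipitations of pooled cells, so an overlap does not show both marks on the same chromatin or in the same cells. Both marks covered the same sequence in 9132 segments totalling 8.75 Mb, with a median segment of 800 bp (quartiles 400 and 1400 bp). Of the H3K4me3 regions, 9007 overlapped H3K27me3 by at least 1 bp, a share of 18.8% (95% Wilson interval 18.4 to 19.1%). Of the H3K27me3 regions, 7027 overlapped H3K4me3, a share of 37.5% (36.8 to 38.2%). The remaining 38921 H3K4me3 regions and 11704 H3K27me3 regions overlapped no called region of the other mark. The shared sequence was 17.4% of the H3K4me3 length and 13.8% of the H3K27me3 length. Random circular shifts of the H3K27me3 regions along their chromosomes gave 1.32 ± 0.118 Mb (SD over 1000 placements, highest 1.70 Mb), so the lists overlapped 6.64 times as much as random placement. The two-sided permutation p was 0.001, the smallest that 1000 placements can give. Shifts of single regions by 0.1 to 1 Mb, which keep each region in its own neighbourhood, gave a ratio of 3.54 with the same p. These p-values describe co-location of the lists and not variation between animals. Random placement treats the lists as called separately, and the sources used here do not say whether they were. Pile-up of reads at the same sequence in both libraries could also give overlaps and was not excluded. Without the regions of identical ends the ratio was 6.43.

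**Figure D1:**
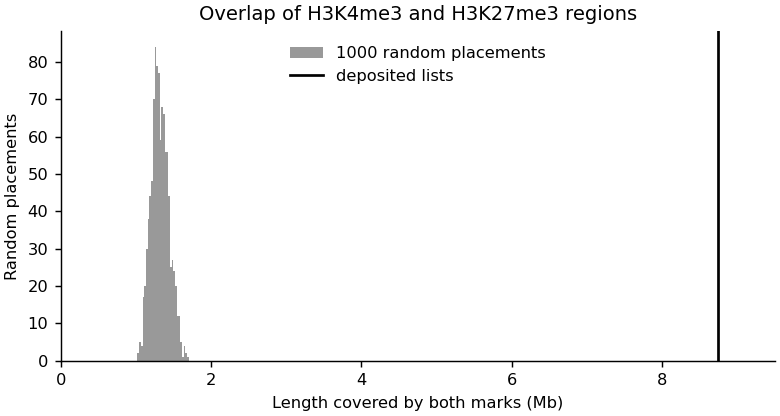
Length covered by both marks, in Mb (x axis), in 1000 random circular placements of the H3K27me3 regions (grey bars, number of placements on the y axis) and in the deposited lists (black line). The observed 8.75 Mb lies above the highest random value of 1.70 Mb.

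Overlapping pairs were usually an H3K4me3 region set inside a wider H3K27me3 region. H3K27me3 regions were wider in general (median 1800 against 800 bp), which favours this arrangement. The share that random placement would give was not computed. Among the 9132 overlapping pairs, the H3K4me3 region lay wholly inside the H3K27me3 region in 6241 (68.3%). The H3K27me3 region lay inside the H3K4me3 region in 933 pairs (10.2%), the pair overlapped in part in 1232 (13.5%), and both regions had identical ends in 726 (7.95%). Most overlapping H3K27me3 regions held a single H3K4me3 region (5879 regions, 83.7%), 722 held 2, 426 held 3 or more, and 9 held 10 or more. In the 1157 H3K27me3 regions of at least 5 kb with a single, fully enclosed H3K4me3 region, the centre of the H3K4me3 region fell within the central 33.3% of the width in 52.4%. Random positions inside the same regions gave 41.2% ± 1.39 (SD over 1000 draws; two-sided permutation p = 0.001, the smallest these draws can give).

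Regions that overlapped a called region of the other mark were wider than regions that did not. H3K27me3 regions that overlapped H3K4me3 had a median width of 2600 bp (quartiles 1000 and 5800 bp), against 1400 bp (800 and 2800 bp) for those that did not. H3K4me3 regions that overlapped H3K27me3 had a median width of 1000 bp (400 and 1600 bp), against 600 bp (200 and 1400 bp). Both differences gave p = 1e-05 in two-sided permutation tests, the smallest that 100000 resamples can give. Wider regions also meet the other mark more often by chance: randomly placed H3K27me3 regions had median widths of 3937 bp with and 1600 bp without H3K4me3, so the observed H3K27me3 difference was smaller than random placement gave. For H3K4me3 the random medians were 896.5 bp with and 800 bp without the other mark, closer together than the observed 1000 and 600 bp. The H3K4me3 difference fell to 200 bp among regions wider than 400 bp (permutation p = 0.242).

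The share of regions overlapping the other mark changed with width in different ways for the marks. H3K4me3 regions of 1000 to 1200 bp overlapped H3K27me3 most often, in 26.1% (95% Wilson interval 25.02 to 27.29%). The share was 12.2% (11.6 to 12.8%) for regions of 200 bp and 12.5% (8.06 to 18.9%) for the 144 regions of 6200 bp or more. Random placement gave 3.28%, 2.62% and 6.95% for these classes, so the observed shares were 7.97, 4.67 and 1.80 times random. For H3K27me3 the share was lowest at 1000 to 1200 bp, at 22.5% (20.9 to 24.2%), and rose with width to 74.4% (71.3 to 77.2%) at 10200 to 20000 bp and 94.3% (81.4 to 98.4%) for the 35 regions over 50 kb. Random placement gave 3.72%, 20.1% and 50.3% for these H3K27me3 classes, so the observed shares were 6.06, 3.69 and 1.87 times random. Relative to random placement, the excess was thus smallest in the widest class of either mark. Below 1000 bp the H3K27me3 share was higher again, at 27.04% for 600 to 800 bp and 31.4% for 400 bp. It was 51.4% (48.2 to 54.5%) for the 950 regions of 200 bp, 24.8 times the 2.07% of random placement. Of these 950, 291 had an H3K4me3 region with identical ends.

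**Figure D2:**
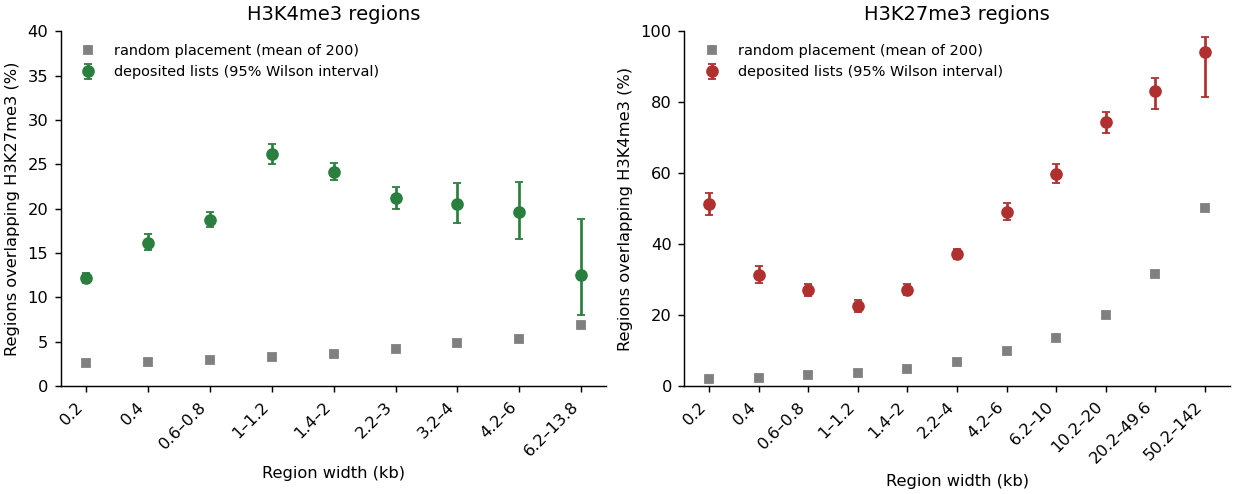
Percentage of H3K4me3 regions overlapping H3K27me3 (left) and of H3K27me3 regions overlapping H3K4me3 (right) on the y axis, by region width in kb on the x axis. Circles show the deposited lists with 95% Wilson intervals and squares the mean of 200 random placements. The H3K4me3 share peaks at 26.1%, and the H3K27me3 share reaches 94.3% in the widest class.

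The widest H3K27me3 regions formed domains of about 100 kb studded with H3K4me3 in some cases and nearly free of it in others. The widest lay on chromosome 15 (102735201 to 102877200, 142 kb) and held 21 H3K4me3 regions. The next were on chromosome 11 (96106601 to 96238800, 132.2 kb, 17 H3K4me3 regions), chromosome 2 (74481401 to 74595000, 113.6 kb, 23 regions) and chromosome 19 (44801801 to 44914800, 113 kb, 5 regions). A region on chromosome 6 (52099401 to 52206600, 107.2 kb) held 24 H3K4me3 regions, which covered 28.4% of its length. By contrast, a second region on chromosome 6 (83309201 to 83414400, 105.2 kb) held 2, a region on chromosome 4 (136480801 to 136571400, 90.6 kb) held 1, and the region on chromosome 5 (120213001 to 120298600, 85.6 kb) held none. The 10 widest also included regions on chromosome 4 (115541001 to 115651400, 110.4 kb) and chromosome 17 (47993201 to 48082400, 89.2 kb), with 10 and 13 H3K4me3 regions. Of 318 H3K27me3 regions over 20 kb, 268 (84.3%) overlapped H3K4me3 and 50 did not, and 17 of those 50 were on chromosome 5. Random placement gave 31.6% for regions of 20200 to 49600 bp and 50.3% for those over 50 kb.

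**Figure D3:**
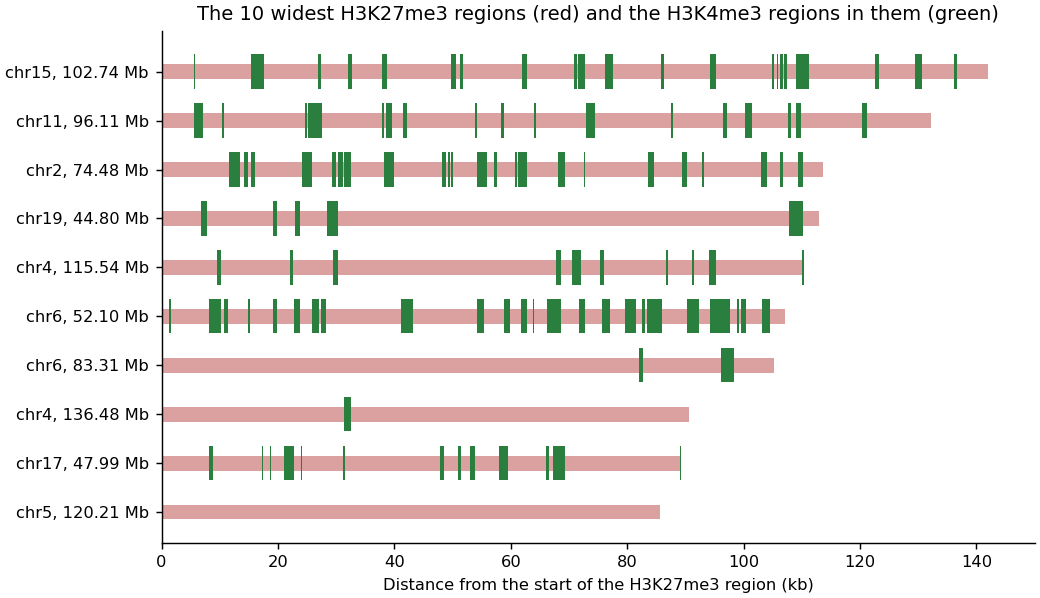
The 10 widest H3K27me3 regions (red bars, labelled by chromosome and mm9 start) drawn to scale from their start, in kb, with the H3K4me3 regions inside them (green). The domains on chromosomes 15, 11 and 2 and the wider domain on chromosome 6 hold 17 to 24 H3K4me3 regions, and the domain on chromosome 5 holds none.

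The longest segments covered by both marks were far shorter than these domains. This follows from the H3K4me3 widths, since a segment cannot exceed its H3K4me3 region and the widest of those was 13.8 kb. The longest was 7.2 kb, on chromosome 2 (115886601 to 115893800), inside an H3K27me3 region of 17.8 kb. Segments of 6.8 kb on chromosome 11 (23976001 to 23982800), 6.6 kb on chromosome 4 (48055401 to 48062000), 6.6 kb on chromosome 6 (127099201 to 127105800) and 6.4 kb on chromosome 14 (70474001 to 70480400) followed. The next 5 measured 5.6 to 5.8 kb and lay on chromosomes 2, 3, 9, 12 and 14. None of the 10 widest H3K4me3 regions overlapped H3K27me3. Among the 144 of 6200 bp or more the share was 12.5%, above the 6.95% of random placement. A set of 10 is too small to show that wide H3K4me3 regions lack H3K27me3. Of the 10, 2 lay on Y, where the H3K27me3 list held 1 region. The widest of the 10 was on chromosome 5 (114575201 to 114589000, 13.8 kb), and others lay on chromosome 2 (162879601 to 162892200, 12.6 kb) and chromosome 9 (114462201 to 114474400, 12.2 kb).

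The marks were also compared between chromosomes. Called regions covered little of the X chromosome: H3K4me3 covered 0.818% of it and H3K27me3 0.841%, against 1.974% and 2.5001% of the autosomes. Relative to its length, X held 0.433 times its share of H3K4me3 and 0.353 times its share of H3K27me3. The regions it did carry overlapped more often. On X, 30.6% of H3K4me3 regions (370 of 1209, 95% Wilson interval 28.1 to 33.3%) overlapped H3K27me3, against 18.5% (18.2 to 18.9%) on the autosomes, where the highest was chromosome 19 at 21.9%. For H3K27me3 regions the share with H3K4me3 was 56.4% (52.3 to 60.4%) on X and 36.9% (36.2 to 37.6%) on the autosomes. The highest autosome here was chromosome 3 at 50.1% (45.9 to 54.2%), whose interval overlapped that of X. Without the regions of identical ends, the H3K4me3 shares were 27.7% (25.2 to 30.4%) and 17.3% (17.0 to 17.6%). With 1 list per mark, no test between chromosomes over replicates could be made. Without read counts the depth on X is unknown, and the sex of the embryos was not examined. Whether depth affected the coverage or the overlap shares of X cannot be told from these values.

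Chromosome 5 stood apart among the autosomes for H3K27me3. H3K27me3 covered 5.31% of it, compared with 4.41% of chromosome 11, the next highest, and 1.09% of chromosome 3, the lowest. Chromosome 5 held 2.23 times its share by length, while its H3K4me3 coverage of 2.14% lay inside the autosomal range of 1.34 to 3.41%. The ratio of H3K27me3 to H3K4me3 length was 2.476 on chromosome 5 and 1.499 on chromosome 4, the next highest. Its H3K27me3 regions overlapped H3K4me3 least often of all autosomes, in 25.6% (23.7 to 27.5%). The excess lay mostly between 111 and 122 Mb, a run of 1-Mb windows above the 95th percentile that was chosen after the values were seen. This stretch is 0.414% of the genome and held 6.22% of all H3K27me3 length (3.93 Mb in 652 regions). The 4 windows of 1 Mb with the most H3K27me3 in the autosomes and X were all inside it, with 762.6, 672.8, 538.6 and 525.6 kb, whereas the median window with any H3K4me3 held 6.4 kb. Without the stretch, chromosome 5 held 1.31 times its share. Of the H3K27me3 regions in the stretch, 17.9% (15.2 to 21.1%) overlapped H3K4me3, against 38.2% (37.5 to 38.9%) elsewhere. Of the H3K4me3 regions of chromosome 5, 20.7% (19.3 to 22.2%) overlapped H3K27me3, against 18.5% on all autosomes. Over the genome that H3K4me3 share was 18.8% with the stretch and 18.6% without it. The low shares of H3K27me3 regions therefore do not show that the marks avoided each other there.

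**Figure D4:**
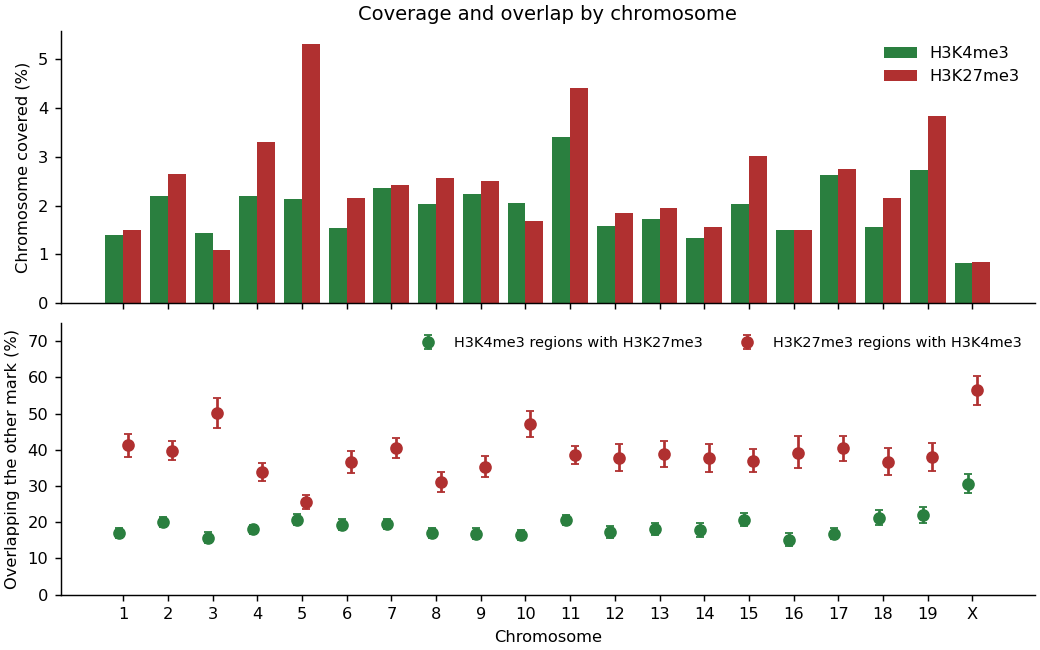
Percentage of each chromosome covered by H3K4me3 (green) and H3K27me3 (red) regions (top), and percentage of regions overlapping the other mark with 95% Wilson intervals (bottom), for the autosomes and X. H3K27me3 coverage is highest on chromosome 5 at 5.31%, and the overlap shares are highest on X at 30.6% and 56.4%.

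**Figure D5:**
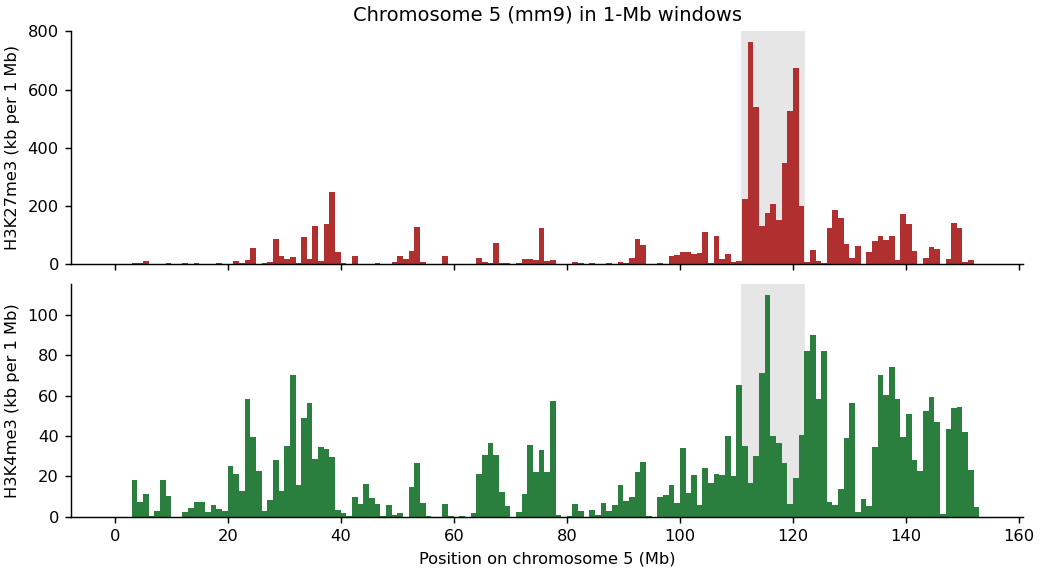
H3K27me3 (top) and H3K4me3 (bottom) in kb per 1-Mb window along chromosome 5 (mm9), with 111 to 122 Mb shaded. H3K27me3 reaches 762.6 kb in a window of the shaded stretch, where H3K4me3 in the same window is 16.8 kb.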

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

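The settings without identical ends, without the stretch of chromosome 5 and with shifts between the first and last region were chosen only after the results were seen. Of 85 values computed under alternatives for 14 results, 71 stayed alike, 13 moved, 1 lost its call and 0 changed direction. For tested values, alike means the same direction and side of the threshold, not the same size. The overlap exceeded random placement under every alternative run, by 3.54 times (single regions shifted by 0.1 to 1 Mb, against 6.64 as reported) to 7.07 times (without chromosome 5 from 111 to 122 Mb). Among regions wider than 400 bp there were 29120 H3K4me3 regions, and the width difference of H3K4me3 regions fell to 200 bp and lost its call. The share of H3K4me3 regions with H3K27me3 became 20.98% among regions wider than 400 bp, 18.4% with regions joined over 1 kb (18.359%), 14.9% with an overlap of 400 bp, 18.0% with an overlap of 50% of the shorter region and 17.5% without identical ends. The share of H3K27me3 regions with H3K4me3 became 30.8%, 41.5%, 30.7%, 35.8% and 34.996% under the same settings in the same order, and 38.2% without the stretch of chromosome 5, which also took the chromosome 5 share of H3K27me3 to 1.31 times its length. The causes were not tested, except that fewer and wider regions enter by construction when narrow ones are left out. Promoter alternatives were not run, because no mm9 annotation was used here, and no replicate could be left out, because each mark has 1 list. Without read counts, depth sets an unknown limit on which regions were called.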

Other observations

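All tests in this part except the number expected on the grid were chosen only after the result was seen.

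Gaps under 1 kb between neighbouring H3K27me3 regions held less H3K4me3 than the H3K27me3 sequence beside them. Of 2564 such gaps, 105 (4.10%) overlapped H3K4me3. H3K4me3 covered 3.55% of the gap length against 12.03% of the 200 bp on each side, a difference of -8.48 percentage points (95% bootstrap interval -9.38 to -7.56, 1000 resamples of gaps). The coverage of the whole genome by H3K4me3 was lower than that of the gaps, at 1.89%. Gaps lie outside H3K27me3 by definition and the sequence beside them inside it, and H3K4me3 covered 13.8% of all H3K27me3 length. The difference therefore largely restates the overlap of the lists and is not separate evidence about gaps.

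The Y chromosome held 33 H3K4me3 regions and 1 H3K27me3 region. Of the 10 widest H3K4me3 regions, 2 lay on Y, within a stretch from 2850001 to 2902600 that held 59.5% of all H3K4me3 length on Y, and 1 lay near the start of chromosome 9 (3015201 to 3028000). The H3K4me3 list also held 1 region on the mitochondrial genome (12001 to 13000).

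Of the 6 widest H3K27me3 regions, 4 lay on chromosomes 15, 11, 2 and 6, which carry the HoxC, HoxB, HoxD and HoxA clusters of homeobox genes that pattern the body axis, and these 4, named after their values were seen, may be the Hox clusters. Random orders of the regions brought all 4 chromosomes into the first 6 in a share of 0.00355 of 100000 draws, and into the first 8, the number needed once regions less than 1 kb apart were joined, in a share of 0.0131; since the order was seen first and set these numbers, chance is not excluded by them. Each of the 4 held at least 17 H3K4me3 regions (up to 24), while the other 6 of the 10 widest held 0 to 13. These counts were known when the 4 were named, so they do not test the hypothesis. A table of assembly GRCm38 lists 9 to 11 protein-coding Hox genes per cluster. Overlap with the genes themselves was not tested, since it needs an mm9 annotation.

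The H3K27me3 excess on chromosome 5 from 111 to 122 Mb was weighed against technical causes. A higher density of promoters in the stretch could raise both marks. Of 2428 other overlapping stretches of 11 Mb, 180, on 12 chromosomes, held at least as much H3K4me3. These held 0.744 ± 0.309 Mb (SD) of H3K27me3, at most 1.68 Mb, against 3.93 Mb. Other stretches with as much H3K4me3 thus held less H3K27me3. Promoter density itself was not measured, and the bound of 5% of stretches was set with their H3K4me3 ranks known, so no conclusion on it is drawn. Extra copies of the stretch that raise the signal of both marks cannot be told apart from a domain of H3K27me3, because called H3K4me3 length also follows promoter density and the input was not analysed here. The H3K4me3 length of the stretch stood at percentile 92.6 of other stretches. Single 200-bp calls made up 31.6% of its H3K4me3 regions (95% Wilson interval 27.5 to 35.9%) against 25.6% elsewhere (25.2 to 26.0%). Within the stretch, the marks peaked in different 1-Mb windows. The windows starting at 112, 120, 113 and 119 Mb held the most H3K27me3. Their H3K4me3 stood at percentiles 57.13, 61.22, 77.02 and 30.96 of windows. H3K4me3 was highest in the windows starting at 114 and 115 Mb (71.4 and 110 kb), where H3K27me3 was 130.8 and 175.2 kb. Promoter density per window was not measured, so these values do not decide on extra copies. No biological explanation was tested.

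The 726 region pairs with identical ends exceeded coincidence on the 200-bp grid, for which permuted widths and random offsets gave an expected number of 117.2 ± 8.53 (SD over 1000 permutations, highest 147.1). That number treats the lists as called separately, and the sources used here do not say whether they were. Of the 726, 440 were 200 or 400 bp wide, and 30.6% of all 200-bp H3K27me3 regions had an identical H3K4me3 region. Their median distance to the next H3K4me3 region was 12400 bp, longer by 1930 bp (95% bootstrap interval 100 to 4000 bp) than for width-matched H3K4me3 regions that were also the single one in their H3K27me3 region, and by 3371 bp (1400 to 5600 bp) than for those among them whose widths in both lists were within 400 bp. Pile-up of reads at the same sequence in both libraries could give such isolated pairs, but so could small isolated sites with both marks, and these values do not separate them. No biological explanation was tested.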
